A study of Mus musculus with 6 samples.

How the data were processed

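RNA was measured in vascular smooth muscle cells (SMC) sorted from the skeletal muscle of male C57BL6J mice that carry the mTmG reporter, which turns on EGFP in cells where Cre has recombined. Per the labels' protocols, muscle was digested to single cells, cells binding antibodies to CD31 (endothelium), CD45 (leukocytes) and Ter119 (erythroid cells) were depleted on magnetic beads, and viable EGFP-positive cells were sorted on 1 of 2 models of flow cytometer; which library came from which sorter is not given in the sources used here. Libraries were made from small amounts of total RNA with a stranded total RNA kit for low input. The submitters' processing notes name Trimmomatic 0.39, STAR 2.6.1d, featureCounts 1.6.5 (part of Subread) and DESeq2 1.18.1, with the mouse builds mm10 and GRCm38.p5, without saying which step each served. Whether duplicate reads were removed, and whether strand was used in counting, is not given in the sources used here.

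The deposited table lists 32179 genes with 1 column for each of 6 libraries. Its values are a score: read counts per gene that the authors divided by 1 factor per library and rounded to whole numbers, as its name and DESeq2 in the submitters' processing notes point to and as the spacing of the low values shows. Every listed gene has a value above 0 in at least 1 library, and 0 mitochondrially encoded genes are listed. The worth of 1 read in each library was found by a grid search on how often each whole number occurs, from 0.6 to 2 in steps of 0.0005. It came to 0.755, 0.9145 and 1.3265 in control libraries 1, 2 and 3 and to 0.831, 0.923 and 1.3995 in KO libraries 1, 2 and 3, so that the table holds an estimated 2935114, 2255115 and 1556750 reads for the controls and 2581454, 2200237 and 1479069 for the KO libraries. All values from 1 to 100 could be reached with these steps. In the 4 libraries where 1 read is worth less than 1, however, rounding maps different read numbers to the same value, so every whole number can be reached there and whole reads were not recovered. These depths are shallow for a test over all genes, and precision is lowest for genes with few reads.

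Groups were taken from the sample descriptions, 3 control libraries and 3 iSM-G5C-KO libraries. The genotype label of the controls is wild type, while every sample's source label says Gprc5c-floxed. The sources used here do not say that the libraries of a group came from separate animals, so p-values measure the spread between these samples, which may be partly technical. Pairs of libraries within a group differed by more than counting noise, with a chi-square per degree of freedom of 3.02 to 10.3 on estimated reads. This argues against repeated sequencing of the same library and does not show separate animals. Each library was counted as 1 replicate. Y-linked genes were read in all 6 libraries and Xist lay between 0 and 4, as the male label requires.

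The main test was limma 3.58.1 in R 4.3.3 on log2(value + 1), with an intensity trend in the prior variance, 2-sided, on the 12735 genes whose mean over all libraries was at least 10, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. For Gprc5c an exact permutation test was added, whose smallest possible p with 3 against 3 libraries is 0.1. A total of 44 gene lists had been fixed, of which the 40 with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01. Camera with a correlation estimated per list and fry, which asks whether a list's genes move on balance 1 way and does not compare them with other genes, were run beside it. The test, the lists, the alternatives and the rule for named genes were chosen before the data were examined. By that rule the text names Gprc5c and its measured relatives. It also considers genes with a mean of at least 50, no overlap between groups and a symbol that is not a predicted-gene name. Of these it names up to 12 per direction past the threshold or, where fewer than 5 pass, the 5 with the smallest p. In each list it names the members that pass, or up to 4 with the smallest p. Some genes that this rule names are not reported here. Enrichment of annotated terms required 20 changed genes in a direction and was therefore not run.

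The groups share replicate numbers. Deviations from the group means of same-numbered libraries correlated over genes at 0.59, 0.31 and 0.44 for numbers 1, 2 and 3, and the highest correlation with another number was 0.16, so the numbers were treated as pairing the libraries. This pairing comes from the data, since no label says what a number marks. The fit with the replicate number as a block is given beside a result where it changes the call. The first principal component held 47.9% of the variance and placed both libraries numbered 1 at 1 end. Depth falls in the same order over the numbers in both groups, so number and depth cannot be separated.

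The fits were tested on simulated libraries with the depths, means and median dispersion of the deposited ones. Of the genes changed 1.5-fold, 26.9% were recovered among 12717 genes tested; of those changed 2-fold, 94.0%; and of those changed 4-fold, 100%. There were 5 false calls among 12517 unchanged genes. The block gave 25.4%, 92.5% and 100% with 4 false calls. A list moved 2-fold was called by both versions of camera, with 0 calls among 39 other lists. Genes were drawn independently, so this does not test lists whose genes move together. The interferon list had an estimated correlation of 0.63 in the deposited values. The simulation had no structure shared between libraries and a median within-group SD of 0.23 (log2), against 0.26 in the deposited values. Every simulated gene had the same dispersion, and only genes with a mean of at least 50 were changed. These shares are thus no measure of what the deposited libraries could detect. There, Cd300a at 4.83-fold and Ifit1 at 3.35-fold had adjusted p of 0.0919 and 0.999 with limma and no block.

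Gene lengths and GC content came from GENCODE M21 on GRCm38, which held 99.8% of the gene identifiers. Coordinates are those of the deposited table. Alternatives covered the pseudocount (0.5 and 5), the filter (none, or a mean of at least 50), quantile, upper-quartile and total scaling, and removal of haemoglobin and rRNA-linked genes. Others were limma without trend, with robust variance and with sample quality weights, the replicate block, a minimum absolute log2 fold change of 1, and leaving out each library.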

Results

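Bulk RNA sequencing compared SMC from the skeletal muscle vasculature of control mice with SMC of tamoxifen-induced iSM-G5C-KO mice, in which the orphan G protein-coupled receptor GPRC5C was depleted from smooth muscle. There were 3 libraries per group, at an estimated 1479069 to 2935114 reads each. All libraries but 1 had 20481 to 21179 genes above 0, and control library 3 had 29707, of which 7733 were listed at a value of 1, against 2734 to 3867 in the others. The question was how loss of GPRC5C alters gene expression in these cells.

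Gprc5c itself (ENSMUSG00000051043, chromosome 11, 114851173 to 114872617, plus strand, GRCm38) had lower values in every KO library than in any control. Normalised counts were 428, 532 and 497 in control libraries 1, 2 and 3 and 328, 305 and 360 in KO libraries 1, 2 and 3. The means were 485.7 ± 52.9 (SD, n = 3) and 331 ± 27.6 (SD, n = 3), so the KO libraries kept 68.2% of the control level. The log2 fold change was -0.55 with a standard error of 0.13. It did not pass limma's test over all genes (adjusted p = 0.999, unadjusted p = 0.00323), nor with the replicate number as a block (adjusted p = 0.142). The exact permutation p was 0.1, the smallest that 3 against 3 libraries allow. Which exons were deleted is not given in the sources used here, and whole-gene counts can keep reads from exons that remain. Its relative Gprc5b, another orphan receptor of the family, was at 302.7 ± 90.2 (SD, n = 3) in controls and 253.7 ± 78.3 (SD, n = 3) in KO libraries, with a log2 fold change of -0.25 and an adjusted p from limma of 0.999. Gprc5a and Gprc5d were at or below 12 in every library and were not tested.

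**Figure D1:**
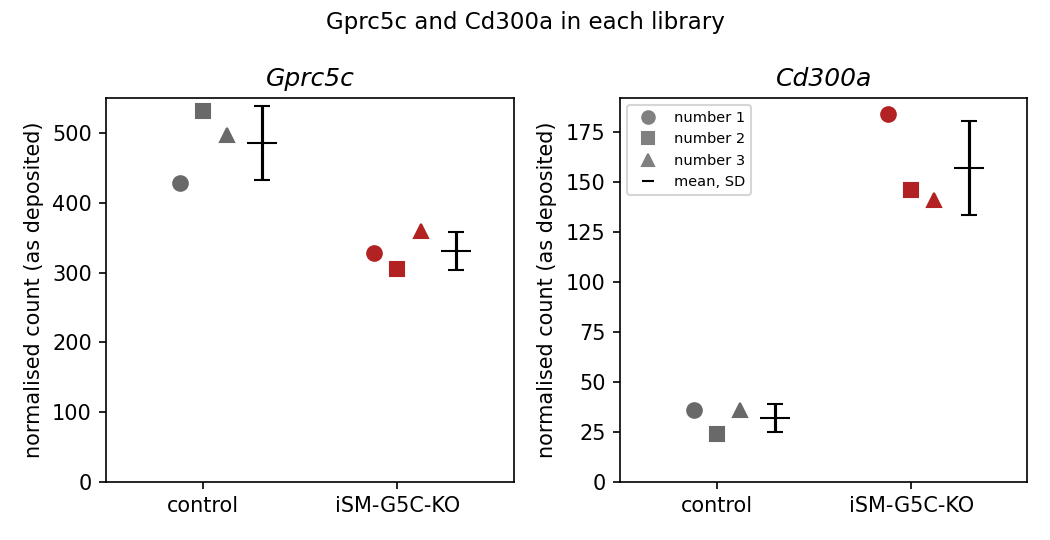
Normalised counts of Gprc5c and Cd300a (vertical axes) in each control and iSM-G5C-KO library, with marker shapes for the replicate number and the mean with SD at the right of each group. All KO values of Gprc5c, 305 to 360, lie below all control values, 428 to 532, and all KO values of Cd300a, 141 to 184, lie above all control values, 24 to 36.

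The gene with the smallest p was Cd300a (ENSMUSG00000034652), which encodes an inhibitory receptor best known from leukocytes. Its values were 36, 24 and 36 in control libraries and 184, 146 and 141 in KO libraries, a log2 fold change of 2.27 with a standard error of 0.21. Adjusted p was 0.0919 with limma and no block, which misses the threshold, and 0.00407 with the replicate block, which passes it. Cd300a lies on chromosome 11 from 114890041 to 114904654 on the plus strand, 17424 bp downstream of Gprc5c on the same strand. Further downstream lie other Cd300 receptor genes on the minus strand, of which Cd300lb, Cd300ld and Cd300lf were at or below 13 in every library (named after their values were seen).

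Over all 12735 tested genes, 0 genes passed an adjusted p of 0.05 with limma and no block, and with the replicate block 1 gene did, Cd300a. At an unadjusted p under 0.05 there were 230 genes, 131 higher and 99 lower in KO libraries, where chance alone gives 636.75 on average. With the block there were 1305, of which 546 were higher and 759 lower, against the same 636.75. That balance depended on the setting. With the block, 669 of 1368 were higher with length, GC and density trends removed. With both libraries numbered 1 left out 721 of 1471 were higher, and with both numbered 2 left out 281 of 820. The unadjusted count without a block was 1308 when KO library 1 was left out, 124 without control library 2 and 125 without KO library 3. The balance turned in some of these fits: 623 of the 1308 were higher without KO library 1, and 60 of 170 without KO library 2. The groups did not overlap in 625 genes (4.91%), where chance gives 10% for unpaired libraries. The replicate numbers may pair these libraries, which no label says, and in that case the 2 shares cannot be compared directly.

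Genes with a mean of at least 50, no overlap between groups and no predicted-gene name were ranked by p. Genes under that mean were not ranked, such as Sox9, with an unadjusted p of 0.00141 with limma. After Cd300a, the higher ranked genes with the smallest p were Ifit1 and Ddx58, an interferon-induced RNA-binding protein and the RNA sensor RIG-I. Then came Irf7, a transcription factor of the interferon response, and Lrrc8b, a subunit of volume-regulated anion channels. Ifit1 averaged 29 ± 4.36 in controls and 102.7 ± 33.6 in KO libraries (SD, n = 3 each), and Irf7 47.3 ± 7.37 and 116.7 ± 43.2. Ddx58 averaged 119.3 and 186, and Lrrc8b 65.7 and 110.0. Among ranked genes, the lower ones with the smallest p were Adamtsl3, an ADAMTS-like matrix protein, Gprc5c, the lysosomal enzyme gene Idua, the collagen-binding integrin subunit gene Itga10, and the fibroblast growth factor receptor gene Fgfr2. Adamtsl3 averaged 88.7 ± 18.9 in controls and 40 ± 12.2 in KO libraries, Fgfr2 81 ± 18.2 and 41.7 ± 13.1, Itga10 112 ± 1.73 and 71 ± 17.5, and Idua 109.3 ± 6.03 and 77.7 ± 6.43 (SD, n = 3 each). Other than Cd300a, each of these genes had an adjusted p of 0.999 with limma and no block, and 0 of them passed with the block.

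Interferon-stimulated genes were the list with the largest difference. Of 24 tested members, 23 were higher in the KO libraries, with a median log2 fold change of 0.91, and camera with the preset correlation called the list higher (adjusted p = 1.44e-25). The call was lost with the correlation estimated from the data (adjusted p = 0.947 with an estimated correlation) and with fry (adjusted p = 0.989). Unadjusted p was 0.0383 with camera and an estimated correlation and 0.0557 with fry. Adjustment over 40 lists gave all 7 called lists the same 0.947. Over all genes tested 0 members passed, and adjusted over the list alone 6 did, among them Ifit1, Ifi44, Irf7, Ifit3 and Rsad2, which rose by 1.74, 2.78, 1.22, 1.37 and 0.89 on the log2 scale. With the replicate block the list-alone count was 20. Ifi44 started from low values, 2, 1 and 8 in controls against 13, 42 and 28. The median difference was 0.21 between the libraries numbered 1, 1.63 between those numbered 2, where proliferation genes also differed most (1.84), and 0.66 between those numbered 3, and the list's median was 0.60 without KO library 2 and 0.50 with the block and both libraries numbered 2 left out.

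**Figure D2:**
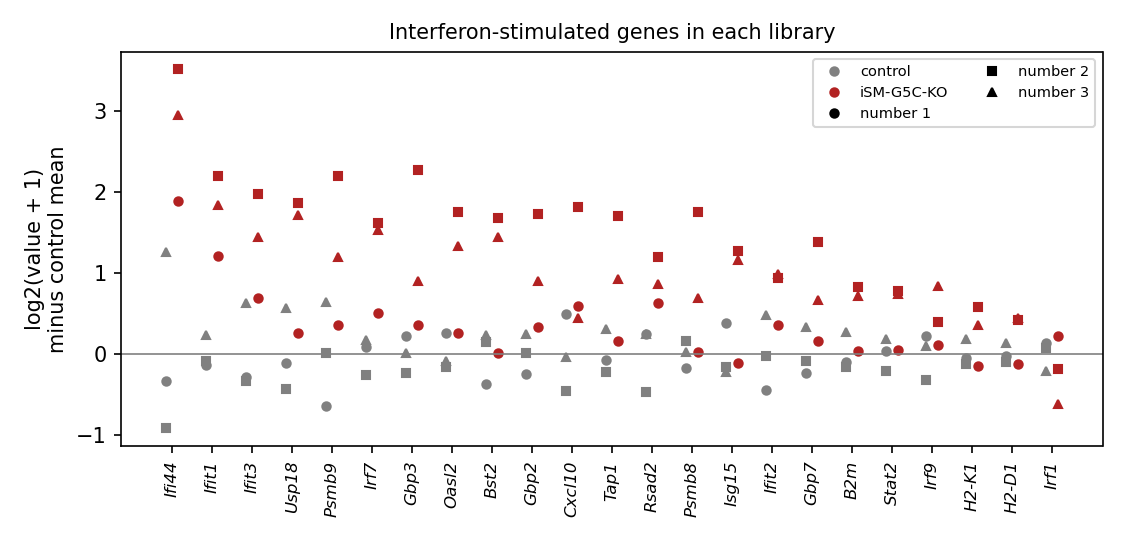
Values of 23 of the 24 tested interferon-stimulated genes (horizontal axis, ordered by log2 fold change) as log2(value + 1) minus the control mean (vertical axis) in every library, control in grey and iSM-G5C-KO in red, with marker shapes for the replicate number. KO library 2 lies above all controls in 22 of these genes, KO library 3 in 21 and KO library 1 in 9.

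Immediate early genes, the transcription factors and phosphatases induced within minutes of stimulation or cell isolation, were lower in the KO libraries. Of 25 members 23 were lower, with a median log2 fold change of -0.26, and the list was called with the preset correlation (adjusted p = 1.25e-08) and not otherwise (adjusted p = 0.947 with an estimated correlation). Egr2 averaged 133.7 in controls and 94.0 in KO libraries, and Fosb 993.0 and 752.3. Over all genes 0 members passed and adjusted over the list alone 0 did, against 10 with the block. The median difference was -0.13, -0.50 and -0.17 between the libraries numbered 1, 2 and 3. The median was -0.17 without KO library 2, -0.40 without KO library 1, -0.12 with the block and both libraries numbered 2 left out, and -0.47 with sample quality weights.

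Contractile genes of smooth muscle were called lower by a small amount. In 21 of 25 members the KO mean was lower on the log2 scale, with a median log2 fold change of -0.09 (adjusted p = 0.0134 with the preset correlation, and adjusted p = 0.947 with an estimated correlation). Ldb3, a Z-disc protein, was at 612, 522 and 369 in controls and 513, 300 and 200 in KO libraries, and Pln, the calcium pump regulator phospholamban, at 392, 296 and 182 against 352, 133 and 99. Both passed adjusted over the list alone with the block (2 members), and 0 members did without it. The median difference was 0.040, -0.21 and -0.059 between the libraries numbered 1, 2 and 3. The list was not called without control library 2 (median -0.079, adjusted p = 0.128), control library 3 (-0.14, 0.0638) or KO library 2 (-0.038, 0.258). It was not called without the expression filter either (adjusted p = 0.235), nor with the block and both libraries numbered 2 left out (-0.0091, 0.253). The median was -0.16 without KO library 1 and, with the list still called, -0.039 with length, GC and density trends removed and -0.19 with sample quality weights.

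The lists of endothelial, pericyte and skeletal muscle fibre genes were called higher. In the endothelial list, whose cells the CD31 depletion was meant to remove, 18 of 19 members were higher, with a median log2 fold change of 0.23 (adjusted p = 0.0133 with the preset correlation, and adjusted p = 0.947 with an estimated correlation). Flt1, a receptor for vascular endothelial growth factor, was at 100, 185 and 241 in controls and 117, 482 and 380 in KO libraries. In the pericyte list 14 of 14 members were higher, with a median of 0.20, among them Abcc9 and Kcnj8, which together form a potassium channel (adjusted p = 0.0328 with the preset correlation, and adjusted p = 0.947 with an estimated correlation). In the list of skeletal muscle fibre genes 18 of 20 were higher, with a median of 0.24 (adjusted p = 0.0206 with the preset correlation, and adjusted p = 0.947 with an estimated correlation). Its members with the smallest p were Ttn and Ryr1, for the giant sarcomere protein titin and the calcium release channel. Ttn was at 422, 442 and 868 in controls and at 660, 1638 and 5386 in KO libraries, with the highest value in KO library 3. In the libraries numbered 3, Ryr1 was at 97 in the control and 494 in the KO library, and the member Neb at 199 and 661. The median difference of the whole list was 0.32, 0.35 and -0.0044 between the libraries numbered 1, 2 and 3. Ttn, Ryr1 and Neb thus did not stand for the list in number 3. The endothelial medians were 0.0094, 0.43 and 0.58 and the pericyte medians 0.11, 0.25 and 0.24. Adjusted over the list alone, and over all genes, 0 members passed in each. With the block 7 pericyte genes, 4 muscle fibre genes and 0 endothelial genes passed over the list alone.

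Leaving out 1 library, without the block, also breaks a pair of libraries with the same number. The endothelial list was then not called without control library 1 (median 0.061, adjusted p = 0.490), KO library 2 (0.17, 0.107) or KO library 3 (0.12, 0.671), and its median was 0.42 without control library 3 and 0.72 without KO library 1. The pericyte median stayed at 0.18 without control library 2 (adjusted p = 0.101) and 0.19 without KO library 2 (0.0619), and was 0.0080 without control library 1 (0.977) and -0.014 without KO library 3 (0.823). It was 0.39 without control library 3 and 0.45 without KO library 1, where the list was called. That list was not called with upper-quartile scaling (adjusted p = 0.0572) or with limma without trend (0.0815), with medians of 0.22 and 0.20. The muscle fibre median was 0.030 without KO library 2 (adjusted p = 0.258), 0.034 without KO library 3 (0.375) and -0.17 without control library 1 (0.470), against 0.44 without control library 3 and 0.59 without KO library 1, where the list was called. With the block and both libraries of a number left out, chosen after seeing the data, the 3 lists were called higher each time with the preset correlation. With number 1, 2 or 3 left out, the medians were 0.48, 0.20 and 0.25 for endothelial, 0.27, 0.18 and 0.17 for pericyte and 0.17, 0.15 and 0.32 for muscle fibre genes.

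Genes of cholesterol synthesis and uptake were higher in 17 of 18 members, with a median log2 fold change of 0.12 (adjusted p = 0.0311 with the preset correlation, and adjusted p = 0.947 with an estimated correlation). Fdft1, the gene of squalene synthase, was at 61, 56 and 52 in controls and 54, 69 and 87 in KO libraries. Over all genes and adjusted over the list alone 0 members passed. Between the libraries numbered 1, 2 and 3 the median difference was -0.19, 0.27 and 0.32, so that of number 1 had the opposite sign. The list was not called without control library 3 (median 0.068, adjusted p = 0.402), KO library 2 (0.010, 0.585) or KO library 3 (0.12, 0.0899), and its median was 0.23 without control library 2 and 0.27 without KO library 1. With the block it was not called when both libraries numbered 2 (0.080, 0.253) or 3 (0.067, 0.590) were left out.

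**Figure D3:**
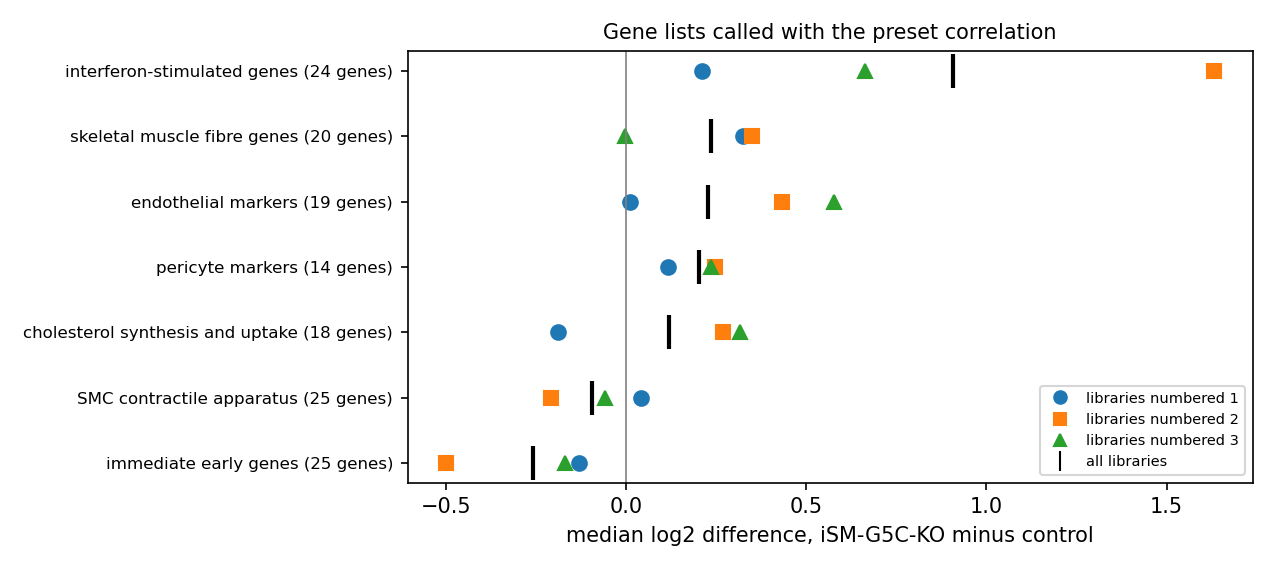
Median log2 difference between iSM-G5C-KO and control (horizontal axis) over the tested members of the 7 called lists, for the libraries of each replicate number (coloured markers) and for all libraries (black bars). The interferon list spreads from 0.21 to 1.63 between numbers, and the median of all libraries lies below 0 for immediate early and contractile genes, at -0.26 and -0.09.

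The other 33 tested lists were not called, with medians from -0.22 to 0.16 and adjusted p from 0.128 upwards. Circadian clock genes, with the lowest median, were not called without the block (adjusted p = 0.371). With it they were called lower with the preset correlation (adjusted p = 0.0419) and not otherwise (adjusted p = 0.822 with an estimated correlation), and between the libraries numbered 3 their median was 0.12. Among regulators of the contractile state, medians were -0.04 for the SRF and myocardin-related list, -0.01 for RhoA and contractile regulators and -0.02 for receptors of vasoactive ligands. Calcium handling and ion channels had a median of -0.06, with 21 of 31 members lower. The cGMP and cAMP pathway had -0.07, with 14 of 21 lower. These 2 medians were close to the -0.09 of the contractile list, which was called. SMC dedifferentiation markers had a median of -0.05. One of them, Sox9, a transcription factor of cartilage, passed adjusted over the list alone (adjusted p = 0.0254 with limma) and not over all genes. Its values were 43, 35 and 46 in controls and 18, 17 and 21 in KO libraries. Fibrillar collagens and matrix had a median of 0.03, basement membrane genes 0.07, TGF-beta and BMP targets -0.05 and inflammatory and NF-kB genes -0.18. Of the other cell types, leukocyte markers had a median of 0.03, fibroblast markers -0.11, satellite cell and myoblast markers 0.03, Schwann and nerve markers 0.04 and adipocyte markers 0.06. Median, mean and test differed in sign for 10 lists, of which 0 were called.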

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

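Removing length, GC and density trends, the block combined with it or with number 1, 2 or 3 left out, and mean-variance weights were chosen after seeing the data; the others were planned. The count of changed genes stayed at 0 in 20 of 25 alternatives. It was 2 with sample quality weights (Cd300a and Ifit1, with 2228 genes at an unadjusted p under 0.05). With the replicate block it was 1, with the block and trends removed 1, and with the block and both libraries numbered 2 left out 1. With the block and both libraries numbered 1 left out it was 17, of which 8 were higher and 9 lower. Among these 17 were the muscle fibre genes Ttn, Neb and Ryr1, the interferon-stimulated genes Ifit1 and Irf7, and Cd300a. The cause of these differences was not tested. The count was 0 whichever single library was left out. Gprc5c was lower throughout, from -0.69 to -0.42, and never passed. The number of called lists was 7. It was 0 with an estimated correlation and 0 with fry, 10 without the expression filter (6 of the 7, without the contractile list, adjusted p = 0.235), 11 with sample quality weights, and 13, 12 and 11 with the block and number 1, 2 or 3 left out; the cause was not tested. Upper-quartile scaling (adjusted p = 0.0572) and limma without trend (0.0815) lost the pericyte call and gave 6 lists. Leaving out 1 library gave 6 to 14 lists, 14 without KO library 1. With 1 library left out, the median of muscle fibre genes ranged from -0.17 (without control library 1) to 0.59, that of pericyte markers from -0.014 (without KO library 3) to 0.45, that of endothelial markers from 0.061 (without control library 1) to 0.72, that of cholesterol genes from 0.010 (without KO library 2) to 0.27 and that of contractile genes from -0.16 (without KO library 1) to -0.038; the cause was not tested. Sample quality weights moved the medians of immediate early, contractile and endothelial genes to -0.47, -0.19 and 0.35. The interferon and immediate early lists were called in 24 of 26 alternatives, all but the estimated correlation and fry. With the block 8 lists were called, the 7 and circadian clock genes; apart from circadian clock genes and Cd300a it changed no call over all genes or over the lists. edgeR, DESeq2 and voom were not run, because rounding leaves reads uncertain by 1 in 4 libraries; upper-quartile scaling stood in for TMM. The background of term enrichment was not varied, as no enrichment was run. In the simulation most 1.5-fold changes were missed at these depths. In the deposited libraries larger changes also missed the threshold without the block, such as Cd300a at 4.83-fold. The 0 called genes therefore do not exclude 2-fold changes.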

Other observations

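The tests on Cd300a, the splits under the block and for the interferon list, the tests on other cell types and on 1 KO library alone for interferon-stimulated genes, and both tests on the densest genes were chosen after the results were seen; removal of length, GC and density trends was added after seeing the data, before its own result was seen. The lists of vasoactive receptors and of PDGF and growth factor signalling were not called, with or without the block. Some of their members passed adjusted over the list alone with the replicate block, and 0 did without it. These members are examples and show no change of a class of genes. Summed over all tested lists 82 members passed so with the block, against 7 without it. Adjusted over all genes tested, 0 members passed with limma, with or without the block. Among vasoactive receptors, with a median of -0.02, 7 of 31 did, 5 higher and 2 lower. Ptgir, the prostacyclin receptor gene, was at 134, 150 and 180 in controls and 194, 238 and 274 in KO libraries (adjusted p = 0.00539 over the list alone with the block), and the endothelin receptor gene Ednrb at 310, 283 and 390 against 360, 480 and 528 (0.0182). The serotonin receptor gene Htr2a was at 63, 40 and 20 against 45, 13 and 4 (0.0182). In the PDGF and growth factor list 6 of 27 passed so, 2 higher and 4 lower. One of them, Pdgfc, a platelet-derived growth factor gene, was at 100, 88 and 62 against 56, 42 and 22 (0.00501).

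Proliferation genes stood apart in 1 library. Their median difference was -0.56 between the libraries numbered 1, 1.84 between those numbered 2 and -0.22 between those numbered 3. The spindle gene Tpx2 was at 34, 32 and 32 in controls and 27, 146 and 36 in KO libraries, and the mitotic kinase gene Plk1 at 6, 5 and 12 against 6, 44 and 7. KO library 2 also had the highest interferon median of the 3 KO libraries over the control mean, 1.64 against 0.26 and 0.90, and Tnc, a matrix gene named after its values were seen, was at 970 there and at 268 to 352 in the other libraries. Whether these differences in KO library 2 share a cause was not tested.

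The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 0 changed genes, which all 10 splits matched, and the highest other split gave 1652. That split sets the 3 deepest libraries (control 1, control 2 and KO 1) against the 3 shallowest, and the first principal component parts the libraries the same way. It also parts control 2 from KO 2, which share a number and have similar depth, at 2255115 and 2200237 estimated reads. The cause of the 1652 genes was not tested. For lists the real split gave 7 with the preset correlation, 7 of the 10 splits gave at least as many, and the highest other gave 15. Under the block, 4 splits part all 3 pairs, again too few: the real one gave 1 gene and the highest other 0 (1 of 4 splits at least as large), and for lists the real one gave 8 and the highest other 10 (3 of 4 at least as large).

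Cd300a was 2.27 higher (log2) in the KO libraries. The tables argue against leukocytes that escaped the CD45 depletion, since the leukocyte list had a median of 0.027 (95% bootstrap interval -0.42 to 0.20), far below the change of Cd300a. Between the libraries numbered 1, 2 and 3 the leukocyte median was -0.14, 0 and 0.13. Bootstrap intervals, here and below, resample genes with the 6 libraries held fixed. They hold no spread between libraries and treat genes that move together as separate. Transcription may run on from the altered Gprc5c gene into Cd300a, the next gene on its strand. None of 9 other tested genes within 500 kb moved by more than 0.43 in either direction, and the next gene on the strand after Cd300a was too low to test, so this cannot be told apart from other effects of the altered allele on its neighbour. An effect of GPRC5C loss itself also stays open, untested.

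Interferon-stimulated genes had a median of 0.91 (0.76 to 1.10), the largest absolute median among the 10 splits (1 of 10 at least as large, highest other 0.84), which is too few splits for a share under 0.05. The split with 0.84 sets the 3 deepest libraries (control 1, control 2 and KO 1) against the 3 shallowest, where the list was higher. Whether depth has a part in the difference between genotypes was not tested. Among the 4 splits that part all 3 pairs, the largest other median in absolute size was -0.70, again with too few splits. Added cells were assumed to raise their own markers about as much as the interferon list, which was not tested. On that assumption the medians argue against endothelial, leukocyte or Schwann cells as the whole cause. The highest upper bound of a median was 0.45, for endothelial markers, but with 1 library left out that median ranged from 0.061 to 0.72. Without KO library 1 it was 0.72 (0.37 to 0.86), against 1.21 (1.02 to 1.56) for the interferon list. The muscle fibre, satellite and adipocyte lists cannot decide. The muscle fibre median was 0.24 (0.08 to 0.32), but a mean control value of 171 could hide a small share. Its members Ttn and Ryr1 rose by 1.72 and 1.50 on the log2 scale. The satellite list shares Des with the contractile list, and its mean control value of 209 could hide a small share. The adipocyte list has 5 tested genes (-1.13 to 0.19). Some pairs stay open, however. Between the libraries numbered 3, endothelial markers differed by 0.58 and the interferon list by 0.66. Between those numbered 1, muscle fibre genes differed by 0.32 and the interferon list by 0.21. More pericytes or fibroblasts cannot be told apart from other causes, because mean control values of 1098 and 591 could hide a small share. The pericyte median was 0.20 (0.16 to 0.27), and the fibroblast median was -0.11 (-0.22 to -0.06), with 14 of 18 markers lower. With length, GC and read density trends removed the interferon list's median was 0.90. With 1 KO library left out it was at least 0.60 (0.48 to 0.74), or 0.50 with the block and both libraries numbered 2 left out. These values argue against such trends and against 1 KO library alone as the whole cause. A difference between the genotypes, and an exposure or handling that differed between samples, stay open and untested, so the hypothesis of an interferon response tied to loss of GPRC5C remains only that.

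The genes with the most reads per kb rose less with depth than others. Over the 6 libraries the median slope of log2 reads on log2 depth was 0.38 (0.21 to 0.57) for the 50 densest genes and 1.07 (0.91 to 1.15) for 42 genes with reads within 0.25 (log2) of theirs but lower density, as a limit on reads per position, such as removal of duplicates by position, could give. The tables argue against a difference between genotypes, since the slope was 0.42 within controls and 0.33 within KO libraries. Depth falls in the same order over the replicate numbers in both groups, so other differences between the numbers could give such slopes too. Gm26917, named after its values were seen, held 796.0 to 870.9 reads per kb in every library while depth ranged 1.98-fold. Among these 50 are 7 of the 25 contractile genes, 4 of the 14 pericyte markers and 4 of the 25 immediate early genes, and fold changes of such genes may be compressed.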
